A study of Arabidopsis thaliana with 96 samples.

How the data were processed

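Small RNA was sequenced from young flowers of Arabidopsis thaliana. Per the labels' protocols, total RNA was extracted from flowers pooled over several lines of the same phenotype for each replicate. Libraries of set A were made with the NEXTflex Small RNA-Seq Kit v3 and those of sets B and C with the Illumina TruSeq small RNA kit. Per the submitters' processing notes, reads were aligned to the TAIR10 genome with Bowtie and counted with HTSeq 0.13.5. Trimming, size selection, alignment options and the handling of reads with several hits are not given in the sources used here. Small RNA kits differ in which sequences they favour, and the set letters mark separate groups of libraries, so comparisons stayed within a set. The exception is a joint fit of B and C, in which each line was taken relative to Col of its own set.

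The deposited table gives, per the file headers, read counts for each library: total reads, reads aligned once, reads aligned more than once, total mapped reads, and reads in the AG enhancer region and in a region named AG promoter or M2. The authors also deposited an overall alignment rate in percent, and RPM (reads per 1000000 mapped reads) for both regions. The mapped count equalled the sum of reads aligned once and more than once in all 96 libraries, and the deposited RPM equalled region reads per 1000000 mapped reads. The deposited percent equalled mapped over total reads within 0.01 points in sets A and C, and stood 0.493 to 0.726 points above it in all 32 libraries of set B. The counts and not the stated percent were used. The meaning of M2 is not given, so the region is called AGp throughout. The 2 kan1-11_ARE//AGe libraries are titled A and B and were taken as replicates 1 and 2 of 1 group, which the labels do not state. Their library codes carry different sample numbers, while the replicates of every other group share a number, so they may be separate samples. Some labels write AGE for AGe, and both spellings were read as one cassette.

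The coordinates in the file headers were compared with a RefSeq copy of the same genome, whose chromosome 4 is 18585056 bp long. AG and its exons were taken from that annotation. The table holds 2 regions and no size classes, strands or other loci, so the size of the reads could not be examined. A transgene copy and the endogenous copy of a region have the same sequence in this reference, and their reads cannot be told apart.

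Changes were tested on the counts with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, two-sided), with total mapped reads as library size. All libraries of a set entered one fit with a mean per group, so that the groups of a set shared the estimate of spread. A common dispersion was used because only 2 regions were measured. Adjusted p are Benjamini-Hochberg values over all tests of a comparison, with a threshold of 0.05. Ratios are of mean RPM, log2 changes and 95% intervals are from the fit. In sets B and C the intervals use more degrees of freedom than the tests (infinite in C), so they are slightly too narrow. Since the low-count hosts and the high-count transgene lines shared 1 estimate, small ratios between tight groups can miss the threshold. Differences that involve a group with a wide spread can pass it. The comparisons, their samples and the alternatives were fixed before the data were examined, apart from the alternatives named below as chosen later. The handling of dispersion was settled on simulated tables before any result was computed. With 30 or fewer measured features the rule for named features was that every feature may be named, and both regions are named.

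The fit was tested on 200 simulated tables per set with the real library sizes. In each table a region took the mean of 1 real group, drawn at random, times a fold between 1 and 4 for each group. All groups had a common dispersion. The far larger differences between hosts and transgene lines, and their unequal spread, were not simulated, so the rates below do not cover them. Among unchanged tests 3.7% in set A, 5.9% in B and 5.4% in C had p under 0.05. A simulated 2-fold change was found in 62.0%, 76.2% and 70.0% of tests, a 1.5-fold change in 24.9%, 33.9% and 34.4%, and a 4-fold change in 96.6%, 99.9% and 99.7%.

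Libraries of a group were compared by a chi-square test over 5 read classes. All 94 pairs differed beyond sampling noise (smallest chi-square 63.0), so none was counted as 1 library deposited more than once. At this depth small shifts between sequencing runs would also be detected, so the test cannot exclude the same RNA sequenced more than once. Replicates are separate pools of lines per the labels' protocols. The p-values rest on a spread between pools that all groups of a set share, not on that of the compared groups alone. Intervals on counts and the limit of 3 reads cover counting error only, since the reads carry no molecular identifiers here.

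Alternatives were total reads as library size, a filter leaving out regions under 10 reads, DESeq2 1.42.0, fits of only the groups compared, the replicate number as a block, and each replicate left out. Alternatives chosen after seeing the data were reads aligned once as library size, limma 3.58.1 on log2(RPM + 1), and the removal of doubted libraries. The doubted libraries of set A were the 3 M318_AGe rMf libraries, with under 50% of reads mapped, and replicate 3 of M317_AGe rMf, with high AGp reads. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The single Col_AGp library entered no test.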

Results

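Small RNA reads over 2 regulatory regions of AGAMOUS were counted in 96 libraries from young flowers of Arabidopsis thaliana. AGAMOUS (AG, AT4G18960) is the MADS-box transcription factor gene that specifies stamens and carpels. The series title speaks of an element that protects regulatory DNA from RNA-directed DNA methylation (RdDM), the plant pathway in which small interfering RNAs guide methylation to matching DNA. The plants carried transgene cassettes or were hosts without a named cassette, taken here as untransformed. The labels name the cassettes AGP//AGe, AGp, AGe, ARE//AGe and Ctr//AGe, and the hosts Col (the Columbia accession), M317, M318 and 6 mutants. Flowers were classed as Wt, sMf, rMf or Sterile. The labels do not spell out sMf, rMf, M317, M318, ARE or Ctr, so these names are used as given. Whether M317 and M318 carry a construct of their own is not stated.

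The 33 groups held 3 libraries each in 31 cases. The kan1-11_ARE//AGe group held 2 libraries and the Col_AGp group 1. Each library came from RNA of flowers pooled over several lines of the same phenotype. In the comparisons below, a line means a host with a cassette, and its flower classes may be pools of different plant lines. The libraries fell into the sets A (28 libraries), B (32) and C (36), and comparisons were made within a set. Mapped reads per library in units of 1000000 reads, ranged from 4.07 to 21.5 in A, from 2.21 to 18.2 in B and from 22.6 to 24 in C. The limit that a count of 0 allows (3 reads) lay between 0.139 and 0.738 reads per 1000000 mapped reads (RPM) in A, between 0.165 and 1.35 in B and between 0.125 and 0.133 in C. Values below are group means ± SD over libraries, in RPM.

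The enhancer region, AGe, spanned positions 10384147 to 10387145 of chromosome 4 (2999 bp, 28.6% GC). In 3 of the 4 annotated AG transcripts 94.53% of it lay in intron 2, 90 bp in exon 3 and the remaining 2.47% in intron 3. In the other transcript it lay wholly in intron 2. The promoter region, AGp, spanned positions 10380701 to 10382800 (2100 bp, 28.6% GC) and ended 56 bp upstream of the annotated start of AG. No gene was annotated within it. Of the 21-base words in the regions, 99.6% for AGe and 99.7% for AGp occurred once in the reference genome. Reads of a transgene copy and of the endogenous copy fall on the same coordinates. The file names this second region as AG promoter or M2 under a single pair of coordinates, so for M317, M318 and their transgene lines it is not certain that the count is of the promoter.

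**Figure D1:**
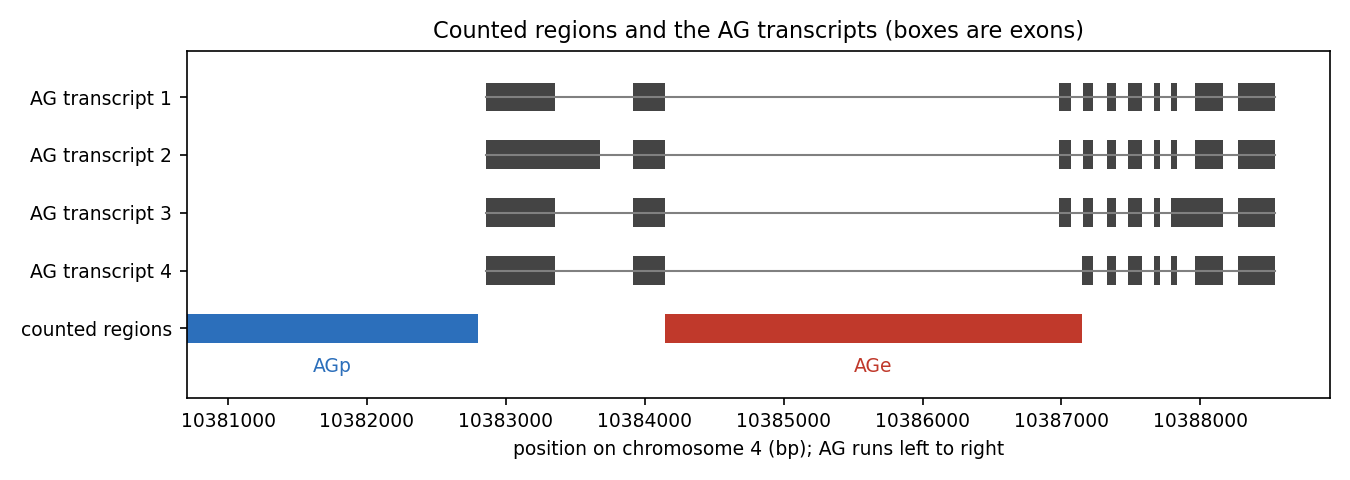
Map of the AGp and AGe regions and the 4 annotated AG transcripts on chromosome 4 (x axis, position in bp; boxes are exons, lines introns). AGe covers intron 2 and AGp ends 56 bp before the first exon.

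Host flowers without a named cassette held at most 18.6 RPM over AGe outside suvh1-2, hdp1-1 and hdp2-1. Flowers with an AGe cassette held between 494 and 5430 RPM over AGe, except with ARE//AGe in Col and kan1-11. AGe rose in 17 of 18 comparisons of a transgene line with its own host and fell in 1. In M318 flowers AGe stood at 15.1 ± 1.69 RPM (n = 3), against 2711 ± 28.7 in M318_AGe sMf and 1523 ± 97.2 in M318_AGe rMf flowers. M317 flowers held 15.9 ± 1.10 RPM, M317_AGe sMf flowers 3423 ± 60.9 and M317_AGe rMf flowers 2022 ± 37.4. The largest ratios were in the Ctr//AGe lines of set C. In Col AGe stood at 1194 ± 10.9 RPM against 1.03 ± 0.143 in the host, or 1164-fold, and in kan1-11 the ratio was 1163. By limma on log2(RPM + 1) these ratios were 592.2 in Col and 600.5 in kan1-11. The hosts were of class Wt, so for lines of class sMf or rMf the cassette and the flower class differ together.

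The change in AGp reads differed with the cassette and with the host. With ARE//AGe in met1-1, ddm1-1, suvh1-2, hdp1-1 and hdp2-1 they rose in 9 of 9 comparisons, for example from 3.77 ± 0.583 to 1834 ± 65.3 RPM in met1-1 sMf flowers. With Ctr//AGe they rose 6.75-fold in met1-1, 6.03-fold in kan1-11 and 6.86-fold in Col, to means of at most 25.5 RPM. Single libraries moved these low ratios: without replicate 2 they were 3.43 in kan1-11 and 4.50 in Col, and without replicate 1 the Col ratio was 10.3. The limma fit on log2(RPM + 1) gave 2.51 in kan1-11 and 2.79 in Col. Per read aligned once the met1-1 ratio was 2.27. In ddm1-1 with Ctr//AGe they stood at 6.82 ± 2.64 RPM against 10.3 ± 5.63 in the host, a difference that did not pass the test (adjusted p = 0.202, edgeR). It passed without replicate 1 (log2 -1.34, edgeR adjusted p = 0.0006) and, with the opposite sign, per read aligned once (log2 1.48, edgeR adjusted p = 0.00161). AGp fell where AGe alone was added to M318 and M317, to 0.0889 and 0.144 of the host level in M318_AGe sMf and rMf flowers and to 0.0458 in M317_AGe sMf flowers. By limma on log2(RPM + 1) these ratios were 0.212, 0.264 and 0.139. Between 40.7% and 47.3% of reads mapped in the M318_AGe rMf libraries, and per total reads their AGe ratio to M318 was 45.6 in place of 101 and their AGp ratio 0.0689 in place of 0.144.

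The single case in which both regions fell was Col_ARE//AGe, whose flowers were Wt. AGe stood at 2.98 ± 0.463 RPM against 10.4 ± 1.69 in Col of the same set, a ratio of 0.287 (log2 change -1.81 ± 0.38 SE, edgeR adjusted p = 2.53e-05). AGp stood at 0.431 ± 0.403 RPM against 5.98 ± 1.55, a ratio of 0.0721 (adjusted p = 2.38e-08 by edgeR), or 0.202 by limma on log2(RPM + 1). These values rest on 18 AGp reads over the 3 Col_ARE//AGe libraries, 1 of which had 0, and the fitted AGp change moved between -4.49 and -2.96 on the log2 scale as libraries were left out. Untransformed Col of set C held 1.03 RPM of AGe and 0.477 of AGp, so both falls are relative to Col of set B only. Whether carry-over raised the counts in Col of set B was not tested. In all, 35 of 36 tests passed (edgeR quasi-likelihood, Benjamini-Hochberg over the 36). The AGp fall in M317_AGe rMf flowers (ratio 0.384) rests on mixed libraries: replicate 3 had 81 AGp reads and replicates 1 and 2 had 4 and 7. It fell short of the threshold without replicate 1 (adjusted p = 0.318) or replicate 2 (adjusted p = 0.400), and without the doubted libraries of set A the log2 change was -4.06. With only its own groups in the edgeR fit the adjusted p was 0.344.

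**Figure D2:**
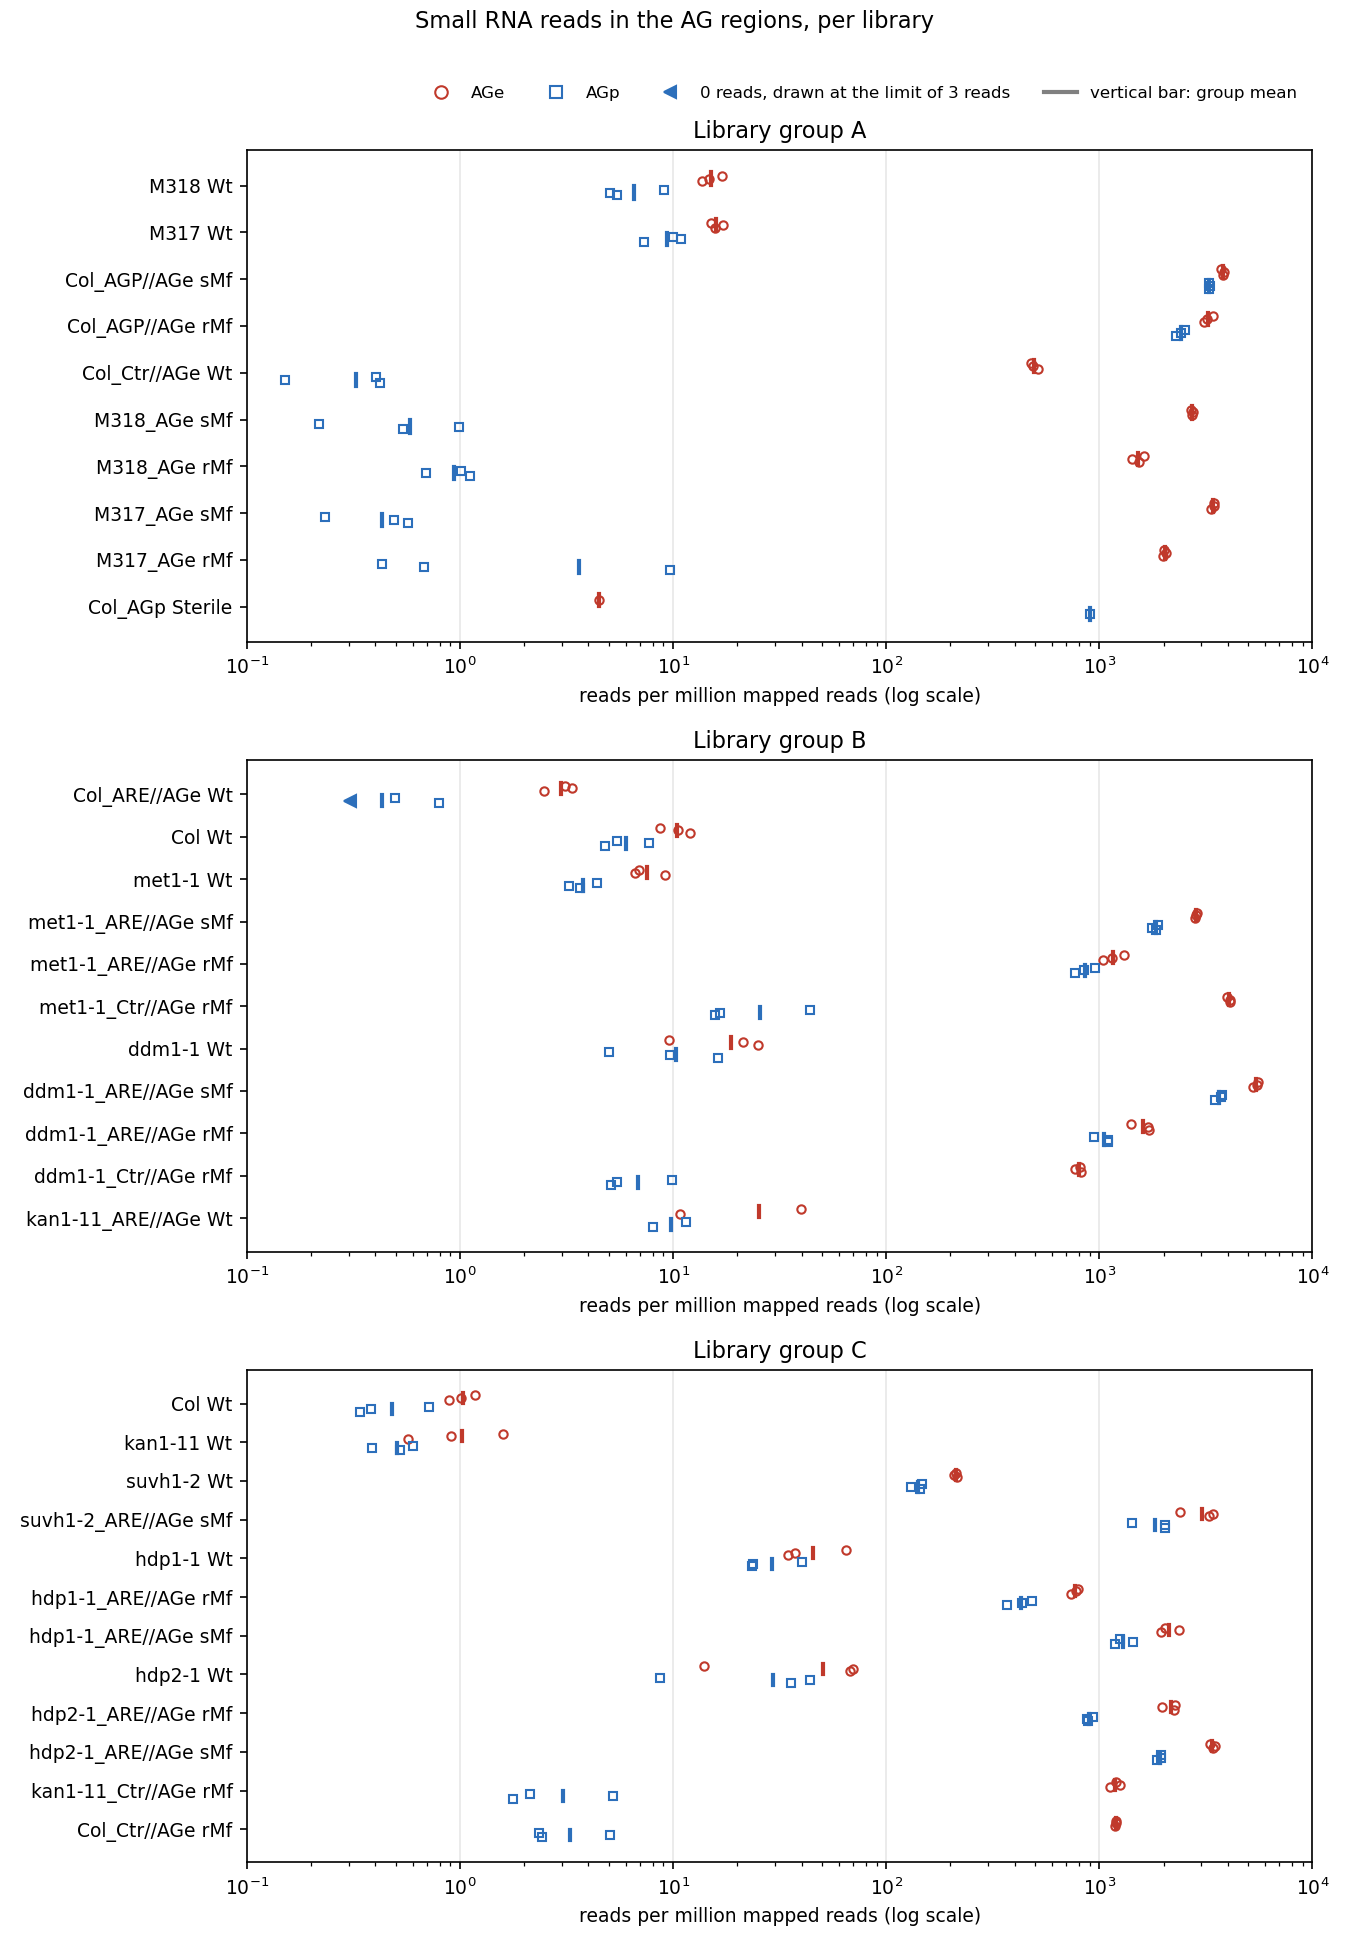
Reads per 1000000 mapped reads (x axis, log scale) over AGe (circles) and AGp (squares) in each library, by group, for the sets A, B and C; bars mark group means and the triangle marks the library with 0 AGp reads at its limit of 3 reads. Col_ARE//AGe lies at 2.98 RPM of AGe, and the ARE//AGe lines of met1-1 and ddm1-1 lie between 1162 and 5430.

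Flowers of class sMf held more AGe reads than rMf flowers of the same host and cassette, here called a line, in 7 of 7 lines. Since each library pooled plants by phenotype, the sMf and rMf pools may hold different transgenic lines. The ratio was 1.17 in Col_AGP//AGe, 1.78 in M318_AGe, 1.69 in M317_AGe, 2.44 in met1-1_ARE//AGe, 3.39 in ddm1-1_ARE//AGe, 2.77 in hdp1-1_ARE//AGe and 1.57 in hdp2-1_ARE//AGe. In ddm1-1_ARE//AGe the means were 5430 ± 156 and 1602 ± 173 RPM (n = 3 each). AGp reads also rose in sMf flowers of the 4 ARE//AGe lines with both classes, by 2.13-fold in met1-1, 3.5-fold in ddm1-1, 3.03-fold in hdp1-1 and 2.14-fold in hdp2-1. In Col_AGP//AGe they stood at 3270 ± 24.3 in sMf and 2406 ± 107 RPM in rMf flowers.

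The AGe difference passed the test in 6 of the 7 lines, and 11 of 14 tests passed in all (edgeR, Benjamini-Hochberg over the 14). In hdp2-1_ARE//AGe the adjusted p was 0.103 for AGe in the edgeR fit over the set, and 4.29e-06 with its own 2 groups alone in the fit. For AGp in Col_AGP//AGe these values were 0.459 and 5.01e-06. Without replicate 3 the AGp differences in met1-1 and hdp2-1 fell short (adjusted p = 0.0785 and 0.0826, edgeR), as did that in hdp2-1 without replicate 2 (adjusted p = 0.0662). The libraries did not overlap in these cases, and 3 against 3 libraries cannot give an exact permutation p under 0.1. Over the 7 lines taken as units, an exact two-sided sign-flip test gave p = 0.0156 for AGe, the smallest it can give, and p = 0.641 for AGp. The AGp fall in M317_AGe sMf flowers (ratio 0.119) rested on replicate 3 of the rMf flowers: without replicate 3 the log2 change was -0.72 (adjusted p = 0.348, edgeR). With only its own 2 groups in the edgeR fit the adjusted p was 0.112, against 0.00168 over the set. Per total reads the sMf to rMf ratio of AGe in M318_AGe was 3.89, the rMf libraries being those with few mapped reads. Per read aligned once, the ddm1-1 ratios became 1.78 for AGe and 1.83 for AGp, and the AGp difference in met1-1 fell short of the threshold (log2 0.59, adjusted p = 0.146 by edgeR).

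**Figure D3:**
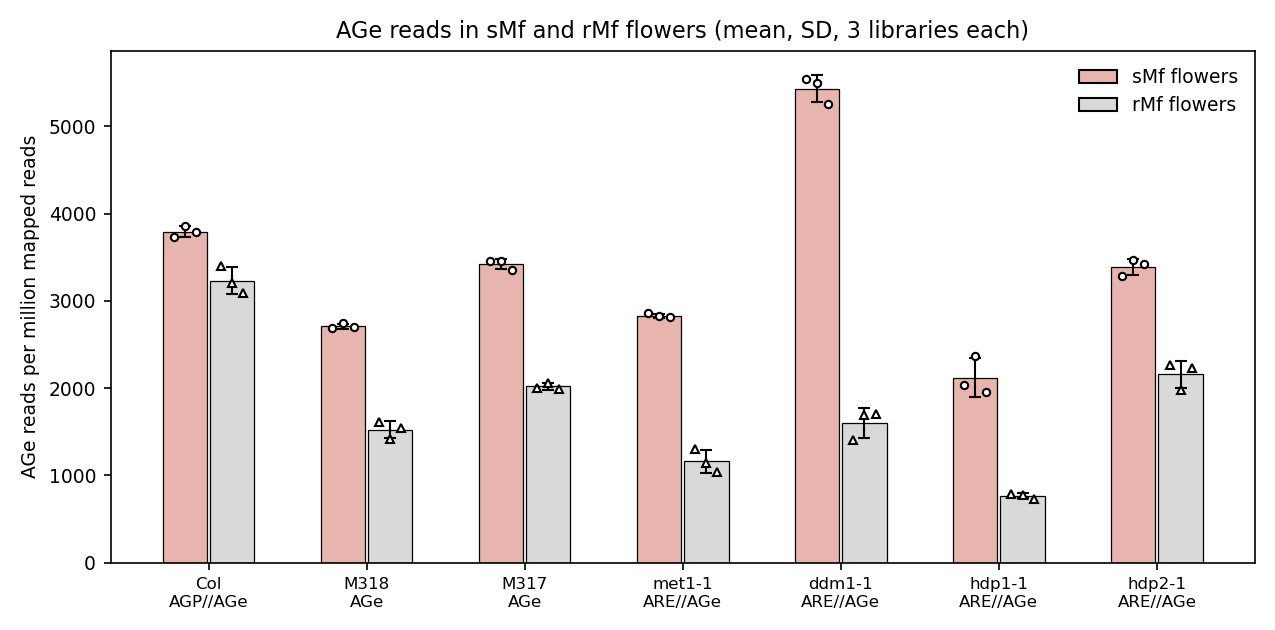
AGe reads per 1000000 mapped reads (y axis, from 0) in sMf and rMf flowers of the 7 lines with both classes; bars are means, whiskers SD and symbols the 3 libraries. In each line every sMf library lies above every rMf library.

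In Col the AGP//AGe cassette went with more AGe and far more AGp reads than Ctr//AGe. AGe stood at 3794 ± 63.2 RPM in sMf and 3229 ± 154 in rMf flowers with AGP//AGe, against 494 ± 20.0 in Wt flowers with Ctr//AGe (n = 3 each), or 7.68-fold and 6.54-fold. AGp stood at 3270 ± 24.3 and 2406 ± 107 RPM against 0.325 ± 0.151. The AGp level with Ctr//AGe rested on 15 reads over 3 libraries, so that the fitted ratio for sMf flowers had a 95% interval of 2242 to 40817. All 4 tests passed (edgeR, Benjamini-Hochberg over the 4), with adjusted p of 9.65e-20 for AGe in sMf flowers. The cassettes differ here together with the flower class, since the Ctr//AGe flowers of this set were Wt.

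In met1-1 and ddm1-1, ARE//AGe was set against Ctr//AGe in the same mutant. The Ctr//AGe flowers were rMf in both mutants, so for sMf flowers with ARE//AGe the cassette and the flower class differ together. MET1 is the maintenance methyltransferase for CG sites and DDM1 a chromatin remodeller needed for DNA methylation. AGp reads rose with ARE//AGe in both mutants, 72.0-fold in sMf and 33.8-fold in rMf flowers of met1-1, and 537-fold and 153-fold in ddm1-1. AGe reads went in opposite directions. In met1-1 they fell to 0.287 of the Ctr//AGe level in rMf flowers, at 1162 ± 131 against 4056 ± 85.1 RPM, and stood at 0.698 of it in sMf flowers. In ddm1-1 they rose 6.79-fold in sMf and 2.00-fold in rMf flowers, from 800.1 ± 25.6 RPM in rMf flowers with Ctr//AGe.

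Of these 8 tests 7 passed (edgeR, Benjamini-Hochberg over the 8). The exception was AGe in met1-1 sMf flowers, with an adjusted p of 0.13 by edgeR over the set, 8.36e-06 with only its own 2 groups in the fit and 0.0499 by DESeq2. Without replicate 3 the AGe rise in ddm1-1 rMf flowers fell short (adjusted p = 0.0763, edgeR), and without replicate 1 the AGp ratio in met1-1 sMf flowers was 111. The share of mapped reads aligned more than once differed between the groups, at 74.0% ± 0.791 in met1-1_Ctr//AGe, 86.5% ± 0.832 in met1-1_ARE//AGe rMf, 93.6% ± 0.170 in ddm1-1_Ctr//AGe and 86.7% ± 0.945 in ddm1-1_ARE//AGe rMf flowers. Per read aligned once, an alternative chosen after seeing the data, the ddm1-1 AGe ratio in rMf flowers was 0.966 (adjusted p = 0.885, edgeR), in sMf flowers 1.70, and the met1-1 ratio in rMf flowers 0.551. The AGp ratios were then 64.5 in met1-1 rMf flowers and 137 and 74.5 in ddm1-1 sMf and rMf flowers.

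In Col and kan1-11, ARE//AGe and Ctr//AGe stood in different sets, B and C, so each was set against Col of its own set. In Col the ARE//AGe change minus the Ctr//AGe change was -11.98 ± 0.63 SE on the log2 scale for AGe (edgeR adjusted p = 3.52e-32) and -6.41 ± 0.72 for AGp (edgeR adjusted p = 7.93e-14). For kan1-11, with Col as the reference in both sets, it was -8.90 ± 0.65 for AGe and -1.93 ± 0.67 for AGp (edgeR adjusted p = 5.66e-23 and 0.00491, over these 4 tests). Per read aligned once the kan1-11 values were -7.23 for AGe and -0.28 for AGp (edgeR adjusted p = 1.20e-18 and 0.651). The references themselves differed: untransformed Col held 10.4 RPM of AGe and 5.98 of AGp in set B, against 1.03 and 0.477 in set C. In RPM, AGp stood at 9.78 in kan1-11_ARE//AGe and 3.04 in kan1-11_Ctr//AGe, so the sign of -1.93 comes from the Col references. The ARE//AGe flowers in these comparisons were Wt and the Ctr//AGe flowers rMf, so cassette, flower class and set differ together.

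**Figure D4:**
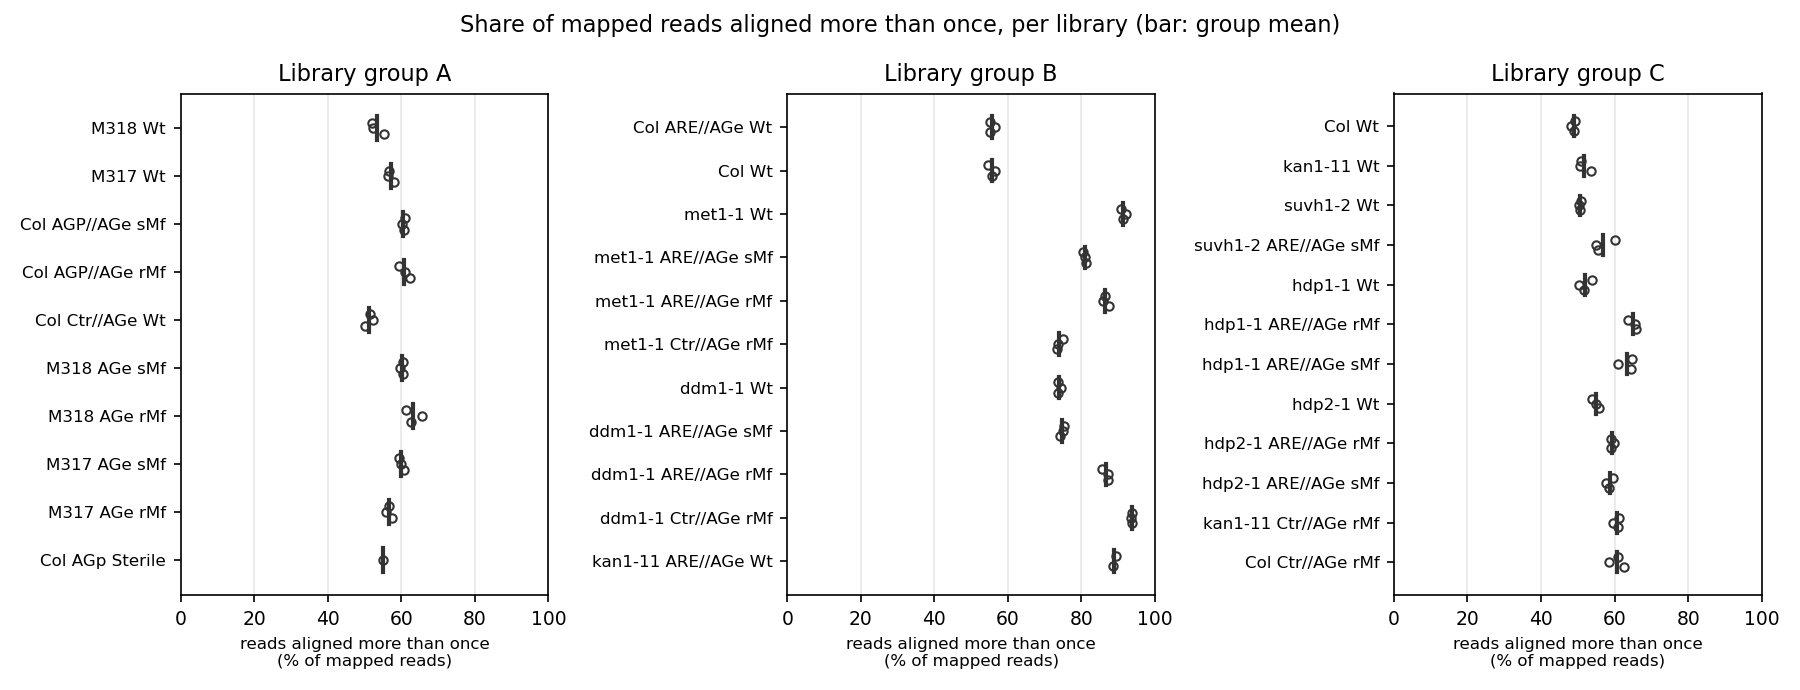
Share of mapped reads aligned more than once (x axis, percent) in each library by group, for the sets A, B and C; bars mark group means. In set B the share runs from 55.6% in Col to 93.6% in ddm1-1_Ctr//AGe.

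Flowers of met1-1, ddm1-1 and kan1-11 with ARE//AGe held more reads over both regions than Col_ARE//AGe flowers, which were Wt, and all 10 tests passed (edgeR, Benjamini-Hochberg over the 10). AGe was 949-fold and 390-fold higher in sMf and rMf flowers of met1-1, and 1821-fold and 537-fold higher in those of ddm1-1. Per read aligned once these ratios were 2195, 1278, 3191 and 1795. AGp was between 1994-fold and 8483-fold higher in these 4 groups, ratios that rest on the 18 AGp reads of Col_ARE//AGe. Without replicate 3 they ran from 3083 to 12770, per read aligned once from 5833 to 13310, and by limma on log2(RPM + 1) from 617 to 2628. In kan1-11, a mutant of the KANADI1 transcription factor gene, the flowers were Wt and the rise was smaller, at 8.48-fold for AGe and 22.7-fold for AGp. The 2 kan1-11_ARE//AGe libraries are titled A and B, not as numbered replicates, and whether they are replicates is not stated. Unlike the replicates of other groups they differ in the sample number of their codes, so they may be separate samples. They held 39.8 and 10.8 RPM of AGe, and without the first the AGe ratio was 3.63, without the second 13.4. Untransformed Col of set B held 10.4 ± 1.69 RPM of AGe, so only the first library stood clearly above it. For AGp the kan1-11_ARE//AGe mean was 9.78 RPM, against 5.98 ± 1.55 in untransformed Col. Both ratios are thus relative to the low level of Col_ARE//AGe. Set B held no kan1-11 host, so a rise over the host was not tested. Without replicate 3 of Col_ARE//AGe the AGp ratio was 33.4, and by limma 7.62. Per read aligned once the ratios were 34.3 for AGe and 81.0 for AGp. In the kan1-11_ARE//AGe libraries 88.9% of mapped reads aligned more than once, against 55.7% in Col_ARE//AGe.

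Without a transgene, suvh1-2, hdp1-1 and hdp2-1 flowers held many more reads over both regions than Col of the same set. SUVH1 binds methylated DNA, and HDP1 and HDP2 derive from transposon proteins and act against silencing. In suvh1-2 AGe stood at 211.7 ± 3.86 RPM and AGp at 140.4 ± 9.08, against 1.03 ± 0.143 and 0.477 ± 0.205 in Col (n = 3), or 206-fold and 294-fold (105 and 96.3 by limma on log2(RPM + 1)). In hdp1-1 the means were 45.4 ± 16.5 and 29.0 ± 9.60 RPM, and in hdp2-1 50.3 ± 31.5 and 29.4 ± 18.4. In kan1-11 they were 1.02 ± 0.522 and 0.505 ± 0.109 RPM.

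Of 12 tests 6 passed, both regions in suvh1-2, hdp1-1 and hdp2-1 (edgeR, Benjamini-Hochberg over the 12). For kan1-11 the 95% interval of the AGe ratio to Col was 0.545 to 1.82. In set B, AGe stood at 7.56 ± 1.37 RPM in met1-1 and 18.6 ± 8.01 in ddm1-1 against 10.4 ± 1.69 in Col, with adjusted p of 0.243 and 0.0580 by edgeR, the second 0.0144 by DESeq2. The met1-1 and ddm1-1 tests, 4 over both regions, changed with replicate 1 and with the library size: without replicate 1 all 4 passed, with AGe lower in met1-1 (log2 -0.53), and per read aligned once all 4 passed with AGe higher in met1-1 (log2 1.90). The replicates of hdp2-1 held 14.0, 69.7 and 67.3 RPM of AGe. Without replicate 1 the AGp ratio to Col was 109 in place of 61.6, and by limma on log2(RPM + 1) it was 17.15.

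No difference was detected between kan1-11 and Col with Ctr//AGe. AGe stood at 1187 ± 61.6 RPM in kan1-11 and 1194 ± 10.9 in Col rMf flowers, and AGp at 3.04 ± 1.91 and 3.27 ± 1.54 (n = 3 each). The AGe ratio was 0.994 with a 95% interval of 0.598 to 1.65, and the AGp ratio 0.929 with an interval of 0.540 to 1.60. Of the 2 tests 0 passed by edgeR after Benjamini-Hochberg adjustment, 0 had an unadjusted p under 0.05 and DESeq2 called 0.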

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

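The tests that weigh explanations in this part were chosen after the results were seen.

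Flowers of suvh1-2, hdp1-1 and hdp2-1 without a transgene held 211.7, 45.4 and 50.3 RPM of AGe on average, where Col and kan1-11 of the same set held 1.03 and 1.02. The lowest of the 9 mutant libraries held 8.79 times the AGe RPM of the highest Col or kan1-11 library. Even carry-over of reads would raise all libraries of the set alike and gives no such difference. The value restates the pattern, however, and is no separate test, and it does not address uneven carry-over. Reads or plants from a Ctr//AGe line are argued against, because the lowest AGp count per AGe read in the 9 mutant libraries was 0.532, against at most 0.00422 in the Ctr//AGe lines of the set. Reads or plants from the ARE//AGe line of the same mutant could give this pattern and cannot be told apart from a mutant effect, which stays open and untested: the mean AGp count per AGe read was 0.634 over the 9 libraries, and the interval of Col, 0.301 to 0.709, covers it. The means were above those of the ARE//AGe lines of the same mutant, at 0.663 against 0.602 in suvh1-2, 0.645 against 0.611 and 0.556 in hdp1-1, and 0.594 against 0.567 and 0.417 in hdp2-1, where only the hdp2-1 libraries overlapped those of its lines.

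AGp reads were lower in M318_AGe and M317_AGe flowers than in M318 and M317. The median AGp RPM of the 6 host libraries was 15.2 times that of the 15 libraries with Ctr//AGe, M318_AGe or M317_AGe. Since 12 of these 15 libraries define the pattern, the value restates it and is no separate test of even carry-over. The 12 M318_AGe and M317_AGe libraries held 151 AGp reads, 81 of them in 1 library, where the host rate at their depth gives 1036. These counts restate the difference in RPM, and argue only against counting error at lower depth as its source. Carry-over into the host libraries from lines rich in AGp reads could play a part and cannot be told apart from a change in the transgene lines, since the pooled AGp counts per AGe read of M318 and M317, 0.399 and 0.600, lie between those of Col_AGP//AGe and of the AGe lines. An effect of the transgene stays open, and so does which sequence was counted in these lines, since the file names the region AG promoter or M2.

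The change from Ctr//AGe to ARE//AGe differed between ddm1-1 and met1-1 in a test of the difference itself. On the log2 scale it was larger in ddm1-1 by 3.28 for AGe and 2.91 for AGp with sMf flowers against rMf flowers of Ctr//AGe, and by 2.81 and 2.19 with rMf flowers in both (edgeR adjusted p of at most 0.000693 over 16 tests). With reads aligned once as library size the AGe difference for rMf flowers went from 2.81 ± 0.48 SE to 0.80 ± 0.51 and no longer passed (edgeR adjusted p = 0.317), nor did the other 3 differences, at 0.85 for AGe and 0.50 for AGp with sMf flowers and 0.21 for AGp with rMf flowers, because the values themselves shrank, which is consistent with the share of reads aligned more than once in the denominator as a source of much of the difference. Unmapped reads are argued against, since the value was 2.73 with total reads as library size. Whether the mutations act differently on the cassettes stays open.

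The step from rMf to sMf flowers was larger in M318_AGe than in Col_AGP//AGe by 0.60 on the log2 scale for AGe (1.73 with total reads as library size, where 40.7% to 47.3% of reads mapped in the M318_AGe rMf libraries), and larger in M317_AGe than in Col_AGP//AGe by 0.53, each in a test of the difference (edgeR adjusted p = 9.33e-06 and 2.98e-05). For AGp the M317_AGe step differed from that of Col_AGP//AGe by -3.50 (edgeR adjusted p = 0.00467), a value that rests on replicate 3 of M317_AGe rMf: without replicate 3 the M317_AGe step was -0.72 in place of -3.06.

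The single Col_AGp library, from sterile flowers, entered no comparison and held 904 RPM of AGp (exact 95% interval 888 to 920) and 4.48 RPM of AGe, where Col_Ctr//AGe libraries of the same set held 0.325 RPM of AGp on average. Reads aligned more than once are part of the mapped reads that served as library size. The share of mapped reads aligned more than once was above Col of set B by 35.8 percentage points in met1-1 and 18.3 in ddm1-1. Relative to Col_ARE//AGe it was higher by 25.2 points in met1-1_ARE//AGe sMf, 30.9 in met1-1_ARE//AGe rMf, 19.1 in ddm1-1_ARE//AGe sMf, 31.0 in ddm1-1_ARE//AGe rMf and 33.3 in kan1-11_ARE//AGe flowers.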

How the results depend on the processing

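Of the 86 single tests, 69 kept their direction and their side of the threshold under all alternatives run. In 4 of the other 17 the value changed sign in some alternative and passed in none: with total reads AGp in M318_AGe sMf against rMf flowers went from -0.76 to 0.35, and as replicates were left out AGe in kan1-11 against Col ran from -0.37 to 0.19, AGp there from -0.14 to 0.34, and AGe in kan1-11 against Col with Ctr//AGe from -0.04 to 0.02. AGp in ddm1-1_Ctr//AGe against ddm1-1 ran from -1.34, without replicate 1, where it passed (adjusted p = 0.0006, edgeR), to 0.15. Replacing mapped by total reads changed 0 calls, as did the limma fit, which was added after seeing the data. By its construction, with 1 RPM added, the limma fit drew ratios with a low group toward 1, as in all 23 of the called ratios that it moved by more than 1.5 times. The filter on low counts removed nothing and so tested nothing. Pseudocounts did not apply to counts, and TMM or size factors from 2 regions were not run. Leaving out each replicate gave 9 to 12 of 14 calls for sMf against rMf flowers, 34 to 35 of 36 for lines against hosts, 6 to 8 of 8 for ARE//AGe against Ctr//AGe, and 6 to 10 of 12 for mutants against Col, where the cause of the 10 was not tested. The counts for AGP//AGe, ARE//AGe in mutants against Col and kan1-11 against Col with Ctr//AGe stayed at 4, 10 and 0.

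With reads aligned once as library size, chosen after seeing the data, mutants against Col also gave 10 calls, and 4 log2 values that passed with one of the library sizes changed sign: AGp in ddm1-1_Ctr//AGe against ddm1-1 (1.48), AGe in ddm1-1_ARE//AGe against ddm1-1_Ctr//AGe rMf flowers (-0.05), and AGe (1.90) and AGp (1.71) in met1-1 against Col. AGe in kan1-11 against Col went from -0.01 to 0.07 and passed with neither. The construction shows the cause, since, for example, 91.4% of met1-1 reads aligned more than once against 55.6% in Col. Without either kan1-11_ARE//AGe library, also an added alternative, AGe in ddm1-1 against Col passed (adjusted p = 0.00531, edgeR), as did AGe in met1-1_ARE//AGe sMf flowers against met1-1_Ctr//AGe (adjusted p = 0.0234, edgeR), through the shared spread. Few reads limit AGp in groups such as M318_AGe sMf, Col_Ctr//AGe of set A and Col_ARE//AGe, with 12, 15 and 18 AGp reads.

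The labels number replicates alike across groups, apart from the single Col_AGp library and from kan1-11_ARE//AGe, whose libraries A and B were taken as 1 and 2. With the replicate block, sMf against rMf flowers gave 11 calls, lines against hosts 35 and mutants against Col 6, the counts without it. On average the same-numbered libraries did not deviate together, with a mean correlation from -0.124 to 0.0194 over the sets and regions. A mean over all groups of a set cannot exclude pairing between particular groups.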

Other observations

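The test of flower class in this part was chosen after the group means were seen. AGp reads per AGe read were far lower with Ctr//AGe than with AGP//AGe or with ARE//AGe in 5 mutants. The means were 0.862 in sMf and 0.745 in rMf flowers of Col_AGP//AGe, between 0.417 and 0.740 in the ARE//AGe lines of met1-1, ddm1-1, suvh1-2, hdp1-1 and hdp2-1, and at most 0.00850 in the Ctr//AGe lines. AGP//AGe and ARE//AGe cannot be compared by it, since Col_AGP//AGe stood in set A and the ARE//AGe lines in sets B and C. Set and kit there differ together with the cassette. The mean was 0.161 in Col_ARE//AGe. Within hdp2-1_ARE//AGe the value was 0.567 ± 0.0241 in sMf and 0.417 ± 0.0230 in rMf flowers, and in met1-1_ARE//AGe it was lower in sMf flowers, at 0.648 ± 0.0212 against 0.740 ± 0.00376 (n = 3 each).

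One hypothesis is that AGe reads go with the flower class across lines, not only within a line. Over the sMf and rMf groups of each set, the mean log2 difference was 1.03, and permuting the flower class among the groups of each set gave an exact two-sided permutation p = 0.0046 over 10500 arrangements. Groups of one line are not independent, so this p partly repeats the difference within lines. Of 22 pairs from different lines of a set, the sMf group was higher in 19. In the other 3 the rMf group was higher: Col_AGP//AGe rMf (3229 RPM) against M318_AGe sMf (2711), met1-1_Ctr//AGe rMf (4056) against met1-1_ARE//AGe sMf (2831), and hdp2-1_ARE//AGe rMf (2157) against hdp1-1_ARE//AGe sMf (2121). In sets B and C every sMf group carried ARE//AGe and several rMf groups carried Ctr//AGe, so in those pairs cassette and flower class differ together. The level may go with the class, and it did not order all pairs of groups.

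The spread of replicates was compared per read aligned once and per mapped read, without a test. Over the 21 groups with at least 1000 AGe reads in each of 3 libraries, the median coefficient of variation of AGe was 2.34% per read aligned once and 3.2% per mapped read, and it was lower per read aligned once in 15 of the 21. In set B it was higher in 4 of 6 groups.

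In kan1-11_ARE//AGe of set B, 88.9% ± 0.554 of mapped reads aligned more than once (n = 2), against 51.7% ± 1.73 in untransformed kan1-11 of set C (n = 3) and 55.7% ± 0.722 in Col_ARE//AGe of set B. The kan1-11 host was sequenced in another set, so the cassette and the set differ together.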
